A study of Mus musculus with 28 samples.

How the data were processed

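Polyadenylated RNA from mouse hippocampus was sequenced in 28 libraries with 14 title stems, each found in both fractions. Per the labels' protocols, hippocampi were dissociated with a kit for adult brain, cells carrying Cd11b were held on magnetic microbeads, and RNA of the held cells and of an aliquot taken before the beads was made into libraries with a directional kit that marks the strand by dUTP. Whether the counting used the strand is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain.

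The authors deposited 2 tables, one per fraction, each with 36172 gene entries, 454 of which share a symbol with another entry. Their raw columns hold estimated counts per gene, in part fractional, on a RefSeq gene model per the file headers. The submitters' processing notes name mm10 and DESeq2; the aligner and counter are not given in the sources used here. The log2 normalized columns deposited beside them were not used. Another 4 columns of per-sample values, from 2 libraries with no sample in the labels, were left out. No gene of the mitochondrial chromosome is in the tables. Coordinates are those of the tables, on mm10; 32891 entries have a gene ID in RefSeq GRCm38.p6, and 99.89% of these overlap that gene.

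Estimated counts were rounded to whole numbers. Groups were taken from the genotype (APP129/PSEN1 or WT) and fraction (input or positive) in the labels of each library, and the letter and number from its title: APP129/PSEN1 input (8), APP129/PSEN1 Cd11b-positive (8), WT input (6) and WT Cd11b-positive (6). Each title stem was taken as 1 animal. The labels do not say whether a stem is a single animal or a pool, so p-values measure the spread between these samples. Library totals ran from 7325213 to 47758703 counts. Deeper libraries measure low genes more precisely, and floors cover counting error only, while bootstrap intervals cover the spread between animals. CPM values use TMM-scaled library sizes within each comparison, so the CPM of a gene can differ slightly between comparisons.

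Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with TMM factors, filterByExpr (minimum count 10), robust dispersion and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. Genotype was tested within each fraction over 14 libraries with the title letter as a covariate. The interaction of genotype with the letter was tested within each fraction, and fraction and its interaction with genotype over all 28 libraries. The fits over 28 libraries held genotype and letter but no term for the animal. They treat the paired libraries of a title stem as independent, and a fit with the animal as a block was an alternative. Adjusted p-values of single genes in the text come from edgeR. Errors after ± are SD for CPM and SE for log2 fold changes. A gene with no count in a group was given a lower bound for its fold, with a floor of 3 counts over that group.

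Before the data were examined, 32 gene lists were fixed from textbook knowledge: MHC-I heavy chains and light chain, MHC-I peptide loading and immunoproteasome, MHC-I receptors, MHC-II, disease-associated microglia, homeostatic microglia, interferon response, complement, senescence, cholesterol synthesis and uptake, lipid droplet and cholesterol efflux, glycolysis, cell cycle, dissociation-induced early genes, transgene-related genes, X-inactivation and Y-linked genes, neurons, astrocytes, reactive astrocytes, oligodendrocytes, their precursors, endothelial, mural, ependymal and choroid plexus cells, border-associated macrophages, monocytes, neutrophils, T, NK, B and erythroid cells, and mitochondrially encoded genes. Of 475 symbols 460 matched, 9 of them by gene ID. Some genes stand in more than 1 list. Lists with at least 3 measured members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. The fry test was run beside it.

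Named genes were chosen by a rule fixed at the same time. In each comparison it takes the 6 MHC-I genes of smallest p, App, Psen1, Prnp and Thy1, the 8 largest increases and 8 largest decreases among called genes with a mean log2 CPM of at least 1 whose symbol is not a Gm, Rik or pseudogene name, and up to 4 members of smallest p from each other list. For the letter interaction it takes called genes, or the 10 of smallest p where more than 10 are called. H2-D1, B2m and H2-K1 in sorted cells, H2-K1 elsewhere, Cd8a and Klrk1 between the fractions, and H2-K1, H2-T23, Psmb9 and Tap1 in the plot of MHC-I levels were added after their values were seen.

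The same title stem in both fractions pairs the samples, since the labels' protocols describe the input as an aliquot of the cells sorted. Of 14 such pairs 13 had a correlation over 0.1 between their residuals from each fraction's genotype and letter fit (range 0.0831 to 0.448).

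The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions. Each gene and each library was drawn independently, so the pairing of the fractions was not simulated. At each fold 48 to 50 genes were changed, in both directions. These are far fewer than were called in the real genotype and fraction comparisons. Of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, edgeR recovered 69.4%, 77.6%, 92% and 100% in the sorted genotype comparison (12452 genes) and 52%, 83.7%, 98% and 100% in the input one (15225 genes), with 3.45% and 3.51% of calls false. Calls were false in 2.94% and 6.42% for the letter interaction in sorted cells and input, 4.84% for fraction and 7.69% for genotype by fraction. DESeq2 1.42.0 had 12.6% and 13.7% of calls false. For the letter interaction edgeR recovered 10.2%, 27.1%, 86% and 79.2% in sorted cells (12932 genes) and 2.08%, 44.9%, 72% and 86% in input (15539 genes), for the fraction comparison 70%, 84%, 100% and 100% (15182 genes), and for the genotype by fraction interaction 42%, 67.3%, 72% and 84% (15463 genes). A changed list was called in each simulation, and 0 of 20 unchanged lists. Simulated genes did not vary together, so this does not test camera on lists whose members do.

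Alternatives were other scaling factors, no or a stricter filter (50 counts in 6 libraries), DESeq2, limma voom, an adjusted p of 0.01, no letter covariate, a replicate block, F or M libraries alone, a covariate for other cell types (sorted) or homeostatic microglia (input), an estimated list correlation and each animal left out. Thinning every library to the smallest of its fraction, the lists and MHC-I member counts under further settings, the fraction fits without the letter, and the overlap of calls between sorted cells of one letter and input of the other were added after the data were seen.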

Results

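RNA was sequenced from hippocampi of mice of the genotype labelled APP129/PSEN1, a model of amyloid deposition named for the amyloid precursor protein and presenilin 1 genes, and of wild-type (WT) mice. Each hippocampus was dissociated, and cells bearing Cd11b, an integrin chain on the surface of microglia and other myeloid cells, were pulled out on magnetic beads. An aliquot taken before the sort was sequenced as the input fraction. The 28 libraries came from 14 title stems, each taken as 1 animal, with 8 APP129/PSEN1 and 6 WT animals in each fraction. Library titles carry a letter, F or M, which splits the APP129/PSEN1 animals 4 and 4 and the WT animals 3 and 3. The labels do not say what the letter stands for. In sorted APP129/PSEN1 libraries the X-inactivation transcript Xist stood at 121.1 ± 129.5 CPM (SD), above the WT mean in 4 of 8. Y-linked Ddx3y stood at 21.59 ± 22.84 CPM, also in 4 of 8. With the letter in the fit their genotype SEs were 0.141 and 0.107 on the log2 scale, so their spread followed the letter. The letter may thus stand for sex. The series title names microglial MHC-I, the surface complex that presents peptides to CD8 T cells, in aging and Alzheimer's disease. The labels give no age for these mice.

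Depth differed with genotype. Sorted APP129/PSEN1 libraries held 35570004 ± 9299834 counts (SD, n = 8, range 20281140 to 47758703) and sorted WT libraries 13100296 ± 3146531 counts (SD, n = 6, range 7325213 to 16601324), a 2.72-fold difference (exact two-sided permutation test over 3003 splits, p = 0.000999). Input libraries held 34351610 ± 8243915 counts (SD, n = 8, range 23371176 to 47625902) in APP129/PSEN1 and 22645664 ± 6134585 counts (SD, n = 6, range 15460801 to 33561055) in WT, 1.52-fold apart (exact two-sided permutation test, p = 0.015). Genes of low level were therefore measured less precisely in WT sorted cells than in any other group.

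The first comparison asked which transcripts the Cd11b sort enriched. Homeostatic microglia genes were higher in sorted cells in 17 of 17 measured members, with a median log2 fold change of 2.05. Tmem119, a microglial surface protein, was higher by 2.08 ± 0.135 (SE) and Itgam, which encodes Cd11b, by 2.10 ± 0.142. Values of this comparison average both genotypes, which differed. From input to sorted cells Tmem119 went from 627.7 to 1920 CPM in APP129/PSEN1 and from 766.1 to 5035 CPM in WT. Itgam went from 716.6 to 2155 CPM and from 372 to 2570 CPM. Border-associated macrophage genes were higher in 11 of 11 members (camera adjusted p = 0.0173; adjusted p = 0.536 with an estimated correlation) and neutrophil genes in 10 of 10 (camera adjusted p = 0.0882). Genes of oligodendrocytes were lower in 14 of 14 members with a median of -9.89, of their precursors in 12 of 12 (-9.64), of neurons in 14 of 14 (-5.70), of endothelial cells in 14 of 14 (-5.50), of ependymal and choroid plexus cells in 10 of 10 (-9.04), of astrocytes in 13 of 14 (-7.44) and of red blood cells in 4 of 4 (-9.51).

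In counts, 12985 of 15338 genes differed between the fractions in 28 libraries, 5746 higher and 7239 lower in sorted cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Gpr17, a receptor of oligodendrocyte precursors, showed the largest fall among the named genes, -12.64 ± 0.27 (adjusted p = 7.94e-25). Grid2, a glutamate receptor subunit, had no count in any sorted library and was at least 1100-fold lower than in APP129/PSEN1 input and at least 394-fold lower than in WT input, taking 3 counts over the group as the floor. Among MHC-I genes 17 of 17 heavy and light chain genes and 14 of 14 peptide loading and immunoproteasome genes were higher (camera adjusted p = 0.00805 and 6.24e-05). With an estimated correlation these were adjusted p = 0.536 and 0.434, while the falls of the oligodendrocyte and precursor lists held (adjusted p = 0.0257 and 0.0104). Of the MHC-I receptors 10 were higher and 3 lower of 13, and the list did not pass (adjusted p = 0.0693, but 0.0409 without APP_PSEN1 replicate F1 and 0.0488 without APP_PSEN1 replicate M3). The lower ones were Cd8b1 (-4.40 ± 0.581), Cd8a (-2.73 ± 0.431) and Klrk1 (-2.33 ± 0.536), the last 2 named after their values were seen; all 3 are known from T cells or NK cells and were under 3 CPM in input. The homeostatic list had camera adjusted p = 2.78e-06, and neurons, astrocytes, endothelial, ependymal and red blood cell lists had 2.44e-05, 2.44e-05, 0.000297, 0.0154 and 0.0347. With an estimated correlation these gave adjusted p = 0.434 for the first 5 and 0.461 for red blood cells. The median of all genes lay at -0.13, at -0.24 with DESeq2 size factors and at -0.31 with library size alone, so the fraction values are relative to that shift. Every list of this comparison had the same counts adjusted over the list alone.

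**Figure D1:**
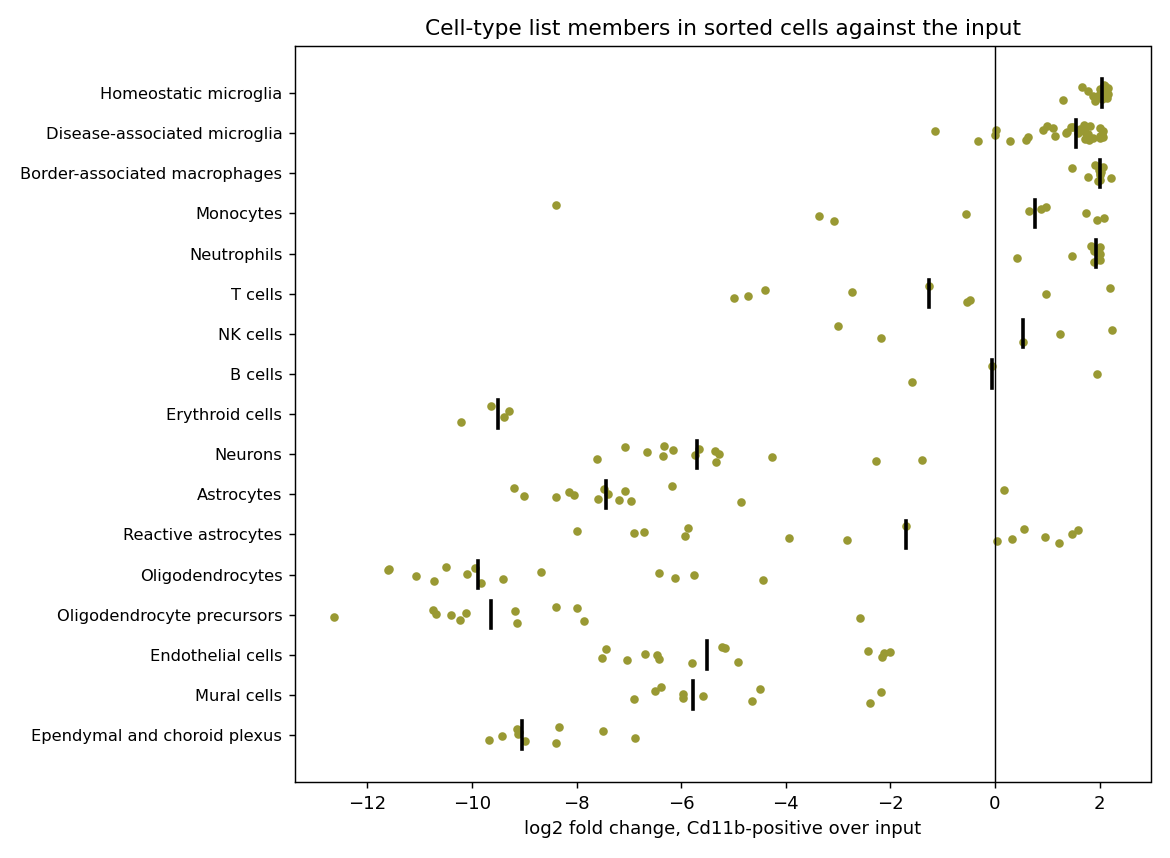
Log2 fold change of Cd11b-positive over input libraries (x axis) for each measured member (points) of 17 cell-type lists, with the list median as a black bar. Homeostatic microglia members sit near 2 and the medians of oligodendrocytes and their precursors at -9.89 and -9.64.

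Genes related to the transgenes were read first, as a check of the genotype labels. App, the amyloid precursor, rose 1.51-fold in input, from 2512 ± 195.5 to 3801 ± 246 CPM, and Psen1, the catalytic subunit of gamma-secretase, 1.49-fold, from 109.9 ± 7.11 to 164 ± 15.4 CPM, each above the WT mean in 8 of 8 libraries. In sorted cells App stood at 738.5 ± 42.9 CPM in APP129/PSEN1 and 715 ± 46.2 CPM in WT (adjusted p = 0.505), and Psen1 at 199.7 ± 9.5 CPM in APP129/PSEN1 and 190.5 ± 11.9 CPM in WT (adjusted p = 0.329). Psen1 was higher in sorted cells than in input (0.68 ± 0.067 on the log2 scale), while App was lower (-1.95 ± 0.0718). The input level of Psen1 thus also depends on the mixture of cells, which weakens it as a check of the labels. Prnp, the prion protein gene, rose 11.3-fold in sorted cells, from 4.43 ± 1.2 to 50.4 ± 9.98 CPM (adjusted p = 1.57e-10), and stood at 1.03 times WT in input (adjusted p = 0.73). Thy1, a neuronal surface gene, fell to 0.598 of WT in input (adjusted p = 2e-04) and was under 1 CPM in sorted cells.

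The second comparison asked how sorted cells differed between APP129/PSEN1 and WT mice. Genes known to rise in disease-associated microglia near amyloid were higher in 30 of 30 measured members. Cst7, an inhibitor of lysosomal proteases on chromosome 2, stood at 689.8 ± 143 CPM (SD, n = 8) in APP129/PSEN1 and 7.24 ± 2.23 CPM (SD, n = 6) in WT sorted cells, 94.9-fold apart. Itgax, the integrin chain Cd11c, rose 13.8-fold from 78.9 ± 10.2 to 1094 ± 183 CPM, and Ctsb, a lysosomal protease, rose 2.29-fold. Homeostatic genes moved the other way, with 13 of 17 lower: Tmem119 fell by 1.37 ± 0.11 on the log2 scale, Selplg by 1.11 ± 0.0836 and Cx3cr1, the fractalkine receptor, by 0.69 ± 0.0734, each below the WT mean in 8 of 8 libraries.

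Altogether 5834 of 12650 genes differed in sorted cells, 3172 higher and 2662 lower, and 931 of the former and 604 of the latter by at least 2-fold (edgeR, adjusted p under 0.05, title letter as a covariate). The disease-associated list passed camera (adjusted p = 8.7e-49; adjusted p = 0.0142 with an estimated correlation). The homeostatic list passed with the preset correlation (adjusted p = 9.99e-10; adjusted p = 0.281 with an estimated correlation). The counts adjusted over the list alone were 30 disease-associated genes higher and 14 homeostatic genes lower. With M libraries alone, 3248 genes were called.

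In the same cells glycolysis genes were higher in 14 and lower in 1 of 16 members, among them Tpi1 (2.54-fold), Aldoa (2.03-fold), Gapdh (2.40-fold) and Hif1a, a hypoxia-responsive transcription factor (3.35-fold); camera gave adjusted p = 3.34e-16, and adjusted p = 0.0815 with an estimated correlation. Genes of lipid droplets and cholesterol efflux were higher in 10 and lower in 1 of 16 (camera adjusted p = 5.12e-09, and adjusted p = 0.0815 with an estimated correlation). Lpl, lipoprotein lipase, was 24.2-fold and the fatty-acid carriers Fabp5 and Fabp3 were 23.3-fold and 311-fold higher. Fabp3 held 6 counts over the WT libraries, so its fold is imprecise. Lpl and Hif1a are also members of the disease-associated list. Cholesterol synthesis and uptake genes were higher in 16 of 18 (adjusted p = 5.94e-05; adjusted p = 0.299 with an estimated correlation), led by Fdps (2.19-fold) and the low-density lipoprotein receptor Ldlr (5.69-fold). The senescence list was higher in 16 and lower in 6 of 31 (adjusted p = 0.00153; adjusted p = 0.296 with an estimated correlation); the chemokine Ccl3 rose 18.3-fold and the urokinase receptor Plaur 10.2-fold, and this list shares Ccl3, Ccl4, Csf1, Spp1 and Timp2 with the disease-associated list. Glycolysis and senescence counts adjusted over the list alone were as above, and on that basis lipid droplet genes were higher in 10 and lower in 2, and cholesterol genes were higher in 18.

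Some MHC-I genes passed in sorted cells, in both directions. Of the heavy and light chain genes 6 were higher, 1 lower and 10 not past the test; of the peptide loading and immunoproteasome genes 4 were higher and 10 did not pass; of the MHC-I receptors 1 was higher, 2 lower and 7 did not pass. H2-D1, a classical heavy chain, rose by 1.01 ± 0.301 (adjusted p = 0.0159), B2m, the shared light chain, by 0.43 ± 0.122 (adjusted p = 0.00942), H2-T22 2.06-fold, Mr1 1.34-fold and the immunoproteasome subunit Psmb8 1.38-fold. H2-D1, B2m and H2-K1 were named for sorted cells after their values were seen. H2-K1, the other classical heavy chain, stood 0.90 ± 0.357 higher and missed the threshold (adjusted p = 0.0572). H2-T24 fell from 145.9 ± 23.2 to 86.5 ± 10.7 CPM, and Pira6 from 3.70 ± 1.09 to 1.99 ± 0.81 CPM. Lilrb4, an inhibitory receptor of the immunoglobulin family, rose 20.2-fold, from 2.57 ± 1.77 to 51.6 ± 29.2 CPM. Whether each gene of the receptor list, Lilrb4 included, binds MHC-I was not examined. Many MHC-I genes, and the Lilr and Pir receptors, have near-identical copies, so the counting can have split reads between them.

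None of the 3 MHC-I lists passed camera in sorted cells (adjusted p = 0.397 for the chains, 0.688 for loading and 0.427 for receptors). The fry test, which asks only whether members move one way, gave adjusted p = 0.128, 0.242 and 0.19. Adjusted over the list alone, 6 chain genes were higher and 1 lower, 3 loading genes higher, and 1 receptor higher and 2 lower. A single library weighed on these values: without WT_positive replicate F2, 24 members in place of 14 passed, and the chain and loading lists had adjusted p = 0.0707 and 0.127. Of all members 8 passed at an adjusted p of 0.01, 6 in F libraries alone, 8 in M libraries alone and 9 with a covariate for the level of other cell types. With that covariate H2-D1 and B2m had adjusted p = 0.0655 and 0.0642, and in M libraries alone 0.176 and 0.122; H2-D1 had 0.0633 in F libraries alone. H2-K1 passed without WT_positive replicate F2 (adjusted p = 0.0145), without WT_positive replicate M4 (0.0232), with DESeq2 (0.0342) and with limma voom (0.0266).

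**Figure D2:**
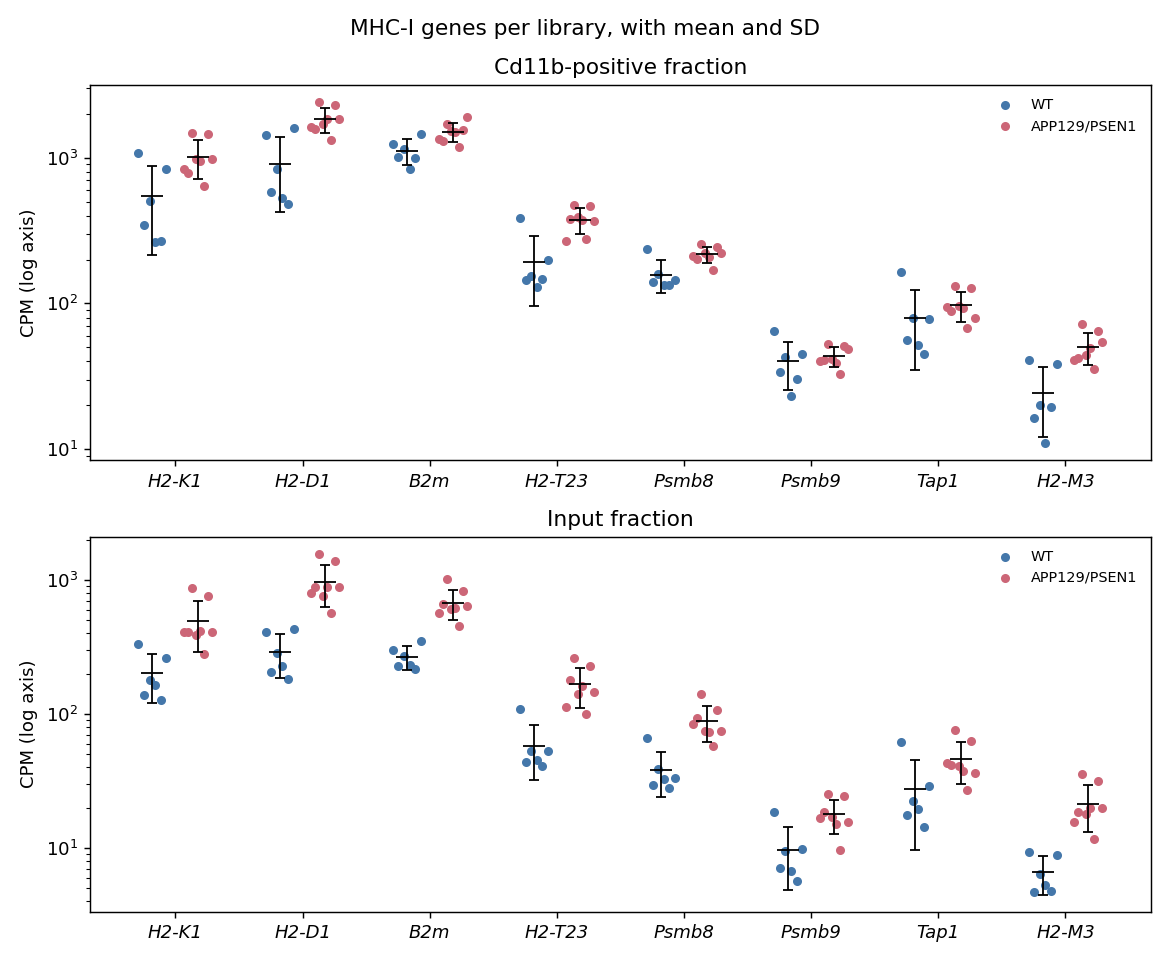
CPM on a log axis of 8 MHC-I genes in each library (points), with mean and SD, for WT (n = 6) and APP129/PSEN1 (n = 8) in sorted cells (upper panel) and input (lower panel). B2m ranges from 834 to 1455 CPM in WT and from 1189 to 1891 in APP129/PSEN1 sorted cells, which overlap, and from 215 to 352 and from 452 to 1019 CPM in input, which do not.

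Of the 8 largest increases in sorted cells, Fabp3 was in a list tested here, that of lipid droplets. Mamdc2 rose 484-fold, from 0.472 ± 0.528 to 223.1 ± 53.7 CPM. Tnfrsf11b, the decoy receptor osteoprotegerin, rose 310-fold and Tmem163, a zinc transporter, 219-fold, from 10 and 26 counts over the WT libraries. Trpm1 and Htatip2 held 2 counts each over the 6 WT libraries, against 2649 and 2205 counts over the 8 APP129/PSEN1 libraries, so no fold is given. Yipf7 and Wif1 had no count in the 6 WT libraries and were at least 105-fold and at least 84.1-fold higher, taking 3 counts over the group as the floor. The largest falls were in U05342 (-8.49 ± 0.289), Mmrn2 (-3.48 ± 0.343), Siglecg, a sialic-acid-binding receptor (-3.26 ± 0.229), Rsc1a1, Ptger3, Rnf150, Steap2 and Abcg3. U05342, on chromosome 19 from 12763528 to 12796123 (mm10), overlaps Zfp91 over 89.5% of its length on the same strand, and Rsc1a1 lies wholly inside Ddi2, so both values are uncertain.

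Markers of other cells in the sorted libraries moved in different directions. Gfap, an astrocyte filament gene, stood at 292.1 ± 87.2 CPM in APP129/PSEN1 and 5.99 ± 2.4 CPM in WT, Cspg4, a proteoglycan of oligodendrocyte precursors, at 218.5 ± 101.6 and 2.56 ± 1.49 CPM, and Flt1, a vascular growth factor receptor, at 200.2 ± 60.5 and 6.40 ± 3.09 CPM, each higher in 8 of 8 libraries. Neuronal genes were lower in 8 of 12 (adjusted p = 0.00883; adjusted p = 0.281 with an estimated correlation), at low levels: Snap25 fell from 5.52 ± 1.66 to 1.38 ± 0.602 CPM. Endothelial genes were higher in 2 and lower in 5 of 12, mural genes lower in 2 of 6, oligodendrocyte genes higher in 1 and lower in 3 of 9 and astrocyte genes higher in 2 and lower in 2 of 12, and none of these lists passed camera (adjusted p = 0.908, 0.266, 0.553 and 0.96). Adjusted over the list alone, 9 neuronal genes were lower, 1 oligodendrocyte gene was higher and 4 lower, and 2 astrocyte genes were higher and 1 lower, while the endothelial and mural counts were as above.

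The third comparison asked the same of the unsorted input. Some MHC-I genes rose in the APP129/PSEN1 input: 10 of 17 chain genes, 9 of 14 loading genes and 2 of 12 receptors were higher and none was lower. Lilrb4 was among these receptors, whose binding to MHC-I was not examined. B2m rose 2.51-fold, from 267.4 ± 52.4 CPM (SD, n = 6) to 673.4 ± 173.2 CPM (SD, n = 8), H2-D1 3.32-fold, H2-M3 3.24-fold, H2-T22 2.21-fold, Lilrb4 19.3-fold and Psme1, a proteasome activator subunit, 1.65-fold, each above the WT mean in 8 of 8 libraries. Of the members 10 passed in F libraries alone and 12 with the homeostatic microglia level as a covariate. H2-K1, named for input after its value was seen, rose by 1.29 ± 0.287 (adjusted p = 0.003; 0.0663 in F libraries alone and 0.0796 with that covariate). The share of input RNA from microglia, estimated in each animal from homeostatic genes and chosen as a measure after the results were seen, was 38.6 ± 6.55% (SD, n = 8) in APP129/PSEN1 and 17.7 ± 1.02% (SD, n = 6) in WT, a ratio of 2.18 (exact two-sided permutation test, p = 0.000333). The chain and loading lists passed camera (adjusted p = 0.000117 and 0.000132), and with an estimated correlation gave adjusted p = 0.469 and 0.461. The receptor list did not pass (adjusted p = 0.167). When adjusted over the list alone, 10 chain genes, 10 loading genes and 2 receptors were higher.

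Disease-associated microglia genes were higher in input as well, where the estimated microglial share was 2.18 times that of WT. Their list was higher in 29 of 30 (adjusted p = 3.22e-60; adjusted p = 0.0516 with an estimated correlation), with Cst7 228-fold, Igf1 53.4-fold, Clec7a, a pattern-recognition receptor, 39-fold, Itgax 26.4-fold and Trem2, a lipid-sensing receptor of microglia, 5.01-fold higher. Homeostatic genes were higher in 7 and lower in 1 of 17 (adjusted p = 0.00205; adjusted p = 0.461 with an estimated correlation), with Hexb 1.65-fold higher and Csf1r at 4110 ± 550.8 against 2735 ± 177 CPM. Complement genes were higher in 9 of 13 (adjusted p = 5.09e-12; adjusted p = 0.202 with an estimated correlation), among them C4b 6.64-fold and C3ar1 5.55-fold. Interferon-response genes were higher in 14 of 32 (adjusted p = 0.000118; adjusted p = 0.616 with an estimated correlation) and MHC-II genes in 4 of 9 (adjusted p = 0.00769; adjusted p = 0.582 with an estimated correlation). Cell-cycle genes were higher in 10 of 20 (adjusted p = 0.00321; adjusted p = 0.461 with an estimated correlation), for example Mki67 1.91-fold and Top2a 1.74-fold. Adjusted over the list alone, 20 interferon-response genes were higher and 1 lower and 11 complement genes higher, and the other lists of this paragraph had the counts above.

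Astrocyte and neuronal genes fell in the input. Astrocyte genes were lower in 14 of 14 (camera adjusted p = 3.96e-12, and 0.202 with an estimated correlation). The glutamate transporter Slc1a2 fell from 4812 ± 789 to 1581 ± 848.5 CPM and Slc1a3 to 0.467 of its WT level. Slc1a3 was also high in sorted cells, where it fell from 1885 ± 213 CPM in WT to 1007 ± 300.5 CPM (edgeR adjusted p = 0.000906). Its fall in input is therefore not read as one of astrocytes alone. The reactive astrocyte gene Gfap rose 3.13-fold, from 566.5 ± 89.9 to 1770 ± 468 CPM, and its list was higher in 5 and lower in 1 of 15 (adjusted p = 0.0383; adjusted p = 0.461 with an estimated correlation). That list did not pass without WT_input replicate F3 (adjusted p = 0.0641) or without WT_input replicate M4 (0.0712). Neuronal genes were lower in 12 of 14 (adjusted p = 4.87e-05; adjusted p = 0.461 with an estimated correlation). Cholesterol synthesis genes were lower in 15 of 18 (adjusted p = 2.48e-10; adjusted p = 0.202 with an estimated correlation), with Cyp51 and Hmgcr at 0.596 and 0.66 of WT. These counts were the same adjusted over the list alone. The estimated microglial share of the same input libraries differed by the ratio of 2.18 given above.

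Apoc4, an apolipoprotein gene, had no count in the 6 WT input libraries and was at least 188-fold higher in APP129/PSEN1, with the same floor of 3 counts over the group. Dcstamp rose 143-fold. Tcap rose 56.3-fold and Klrb1b 44.2-fold, from 20 and 29 counts over the 6 WT libraries. Oca2 rose 93.6-fold (6.55 ± 1.33 on the log2 scale), from 8 counts over the WT libraries and with overlapping groups, so its fold is imprecise. The largest falls were in Olfr287 (-5.82 ± 0.31), Hsd11b1, which regenerates active glucocorticoid (-2.27 ± 0.31), Kirrel2 (-2.25 ± 0.401), Gli1 (-2.18 ± 0.312), AA465934, Rtp1, Dmp1 and Agt, angiotensinogen, which went from 117.6 ± 30.6 to 29.6 ± 13.2 CPM. AA465934 did not pass without APP_PSEN1_input replicates F1, F2, F3 or F4 (adjusted p = 0.0742, 0.0654, 0.0868 and 0.0719) or WT_input replicates F3 or F4 (0.0518 and 0.0543), each left out singly. In all, 5310 of 15330 genes differed, 2761 higher and 2549 lower (edgeR, adjusted p under 0.05). The number called was 2510 in F libraries alone, 2259 in M libraries alone and 1094 with the homeostatic microglia level as a covariate.

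**Figure D3:**
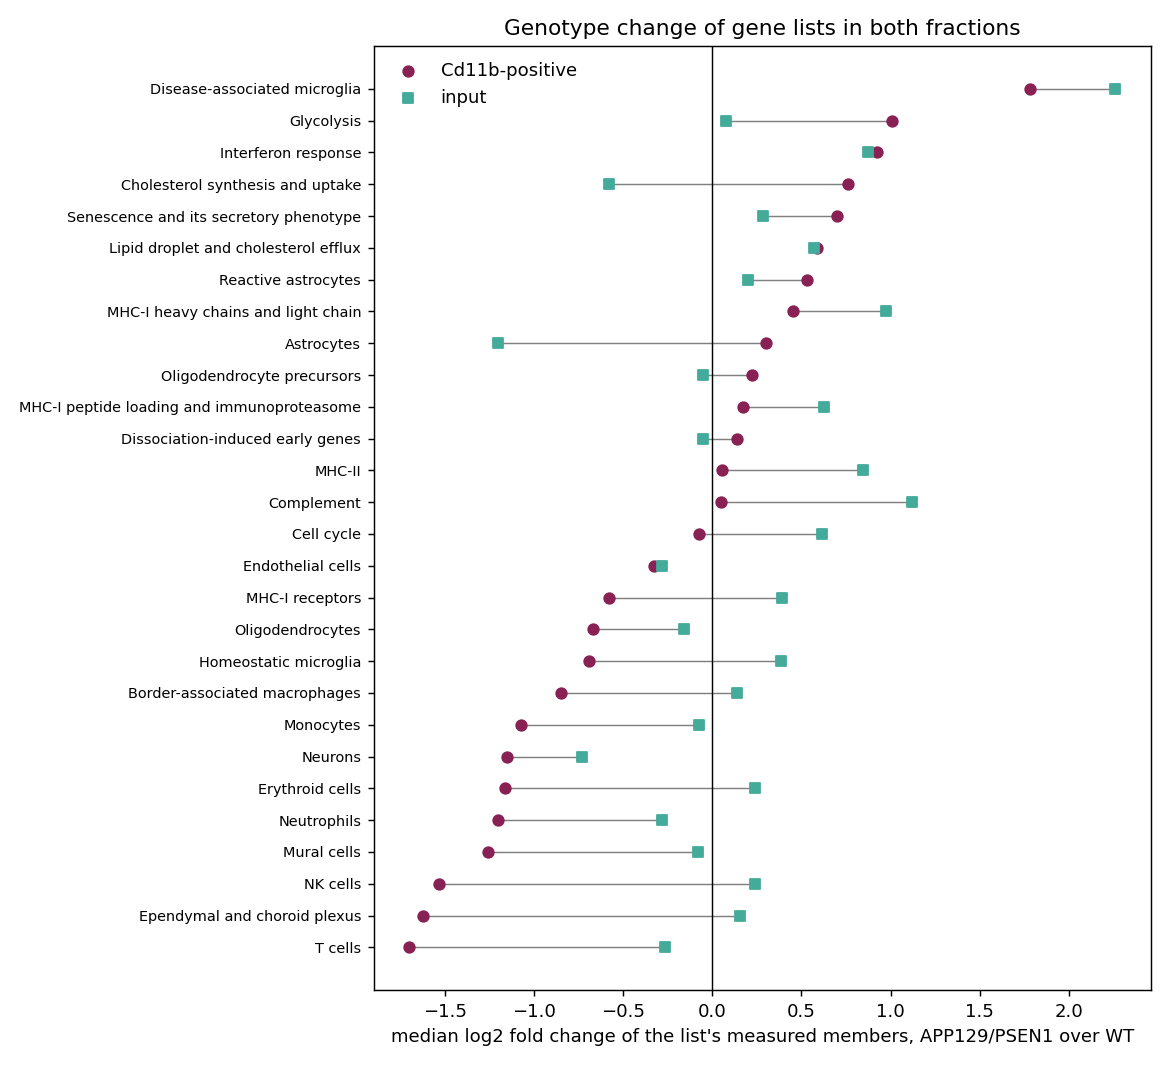
Median log2 fold change of APP129/PSEN1 over WT (x axis) over the measured members of each list, for sorted cells (circles) and input (squares), joined by a line. The disease-associated list lies at 1.78 and 2.26, the homeostatic list at -0.69 and 0.38, and the cholesterol synthesis list at 0.76 and -0.58.

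The fourth comparison tested whether the genotype change differed between the fractions. The genotype difference of cholesterol synthesis genes was more positive in sorted cells than in input in 18 of 18 members, with a median shift of 1.33 on the log2 scale (camera adjusted p = 1.45e-20; adjusted p = 0.0287 with an estimated correlation). Homeostatic genes shifted the other way in 15 of 17, with a median of -1.10 (adjusted p = 1.42e-17; adjusted p = 0.0354 with an estimated correlation), and so did complement genes in 9 of 13 (adjusted p = 1.56e-07; adjusted p = 0.139 with an estimated correlation), C1qa by -1.32 ± 0.14. The estimated microglial share of input RNA was 38.6 ± 6.55% (SD, n = 8) in APP129/PSEN1 and 17.7 ± 1.02% (SD, n = 6) in WT, a ratio of 2.18; it is computed from the same homeostatic genes, so it is not independent of their shift. Glycolysis genes were shifted upward in sorted cells in 12 and downward in 1 of 16 (adjusted p = 7.81e-08; adjusted p = 0.249 with an estimated correlation), and astrocyte genes in 8 of 14 (adjusted p = 4.57e-05; adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, 18 cholesterol genes and 8 astrocyte genes were shifted upward, 16 homeostatic and 11 complement genes downward, and glycolysis genes upward in 12 and downward in 2. Lipid droplet genes were shifted upward in 5 and downward in 2 of 16 (adjusted p = 0.0198; adjusted p = 0.572 with an estimated correlation).

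MHC-I chain genes differed in 1 member upward and 2 downward of 18, loading genes in 7 downward of 14 and receptors in 3 downward of 13, and none of the 3 lists passed camera (adjusted p = 0.577, 0.0604 and 0.289). The loading list passed, downward, without WT replicates F2, M2 or F3 (adjusted p = 0.0218, 0.0361 and 0.0474) or APP_PSEN1 replicates M4 or M3 (0.0367 and 0.0462), each left out singly. B2m rose less in sorted cells than in input (difference -0.94 ± 0.211, adjusted p = 0.00117). H2-T24, which fell in sorted cells and stood 0.21 ± 0.123 higher in input (adjusted p = 0.197), differed by -1 ± 0.159 (adjusted p = 1.93e-05), and the difference for H2-K1 was -0.42 ± 0.436 (adjusted p = 0.503). When adjusted over the list alone, 2 chain genes, 8 loading genes and 3 receptors were shifted downward. Over all genes 4749 of 15555 differed, 1841 upward and 2908 downward (edgeR, adjusted p under 0.05), and 2997 passed at an adjusted p of 0.01.

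Among the largest shifts, Lingo1 stood at 9.94 CPM in APP129/PSEN1 and 0.0716 CPM in WT sorted cells, against 27.8 and 37.3 CPM in input. Sel1l3 stood at 9.35 and 0.0561 CPM in sorted cells and at 11.4 and 11.7 CPM in input (shift 7.33 ± 0.501), and Tmem178 at 16.1 and 0.0688 CPM in sorted cells and 13.3 and 9.51 CPM in input (7.07 ± 0.527). Syngr3, Pkp2 and Meox1 had no count in WT sorted cells and were at least 28.4-fold, 42.4-fold and 11.6-fold higher in APP129/PSEN1 sorted cells, with 3 counts over the group as the floor. Pvalb, Thsd7b and Cpxm2 had no count in APP129/PSEN1 sorted cells and 10, 8 and 9 counts in WT sorted cells. The shift of Cpxm2 did not pass without WT replicates F2, M4 or M2 (adjusted p = 0.179, 0.0777 and 0.0512) or APP_PSEN1 replicate F3 (0.0579). Myzap (-4.35) and Dusp14 (-4.16) rested on a single animal each: without WT replicate M2 the value of Myzap was 0.46, and without WT replicate M3 that of Dusp14 was 1.46.

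Of the 12499 genes tested in both fractions, 1377 were higher and 638 lower in both, against 683 and 392 for independent lists of these sizes. Another 287 were higher in sorted cells and lower in input, and 325 the reverse. The fractions share their animals. With no animal shared, sorted cells of F and input of M libraries, each fitted alone, had 618 genes higher and 166 lower in both, against 223 and 109 for independent lists. For sorted cells of M and input of F libraries these were 660 and 158, against 209 and 85. This comparison was chosen after the overlap was seen. It removes shared animals but not shared cell types, since the input also holds Cd11b-bearing cells. An excess over independent lists can come from those cells, so it does not show that other cells changed alike. Over 99 other splits of the animals by genotype the highest overlap was 0 in either direction, a weak bound, since such splits called at most 1 gene in input.

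The last comparison asked whether the genotype change differed between F and M libraries. No gene passed in either fraction with edgeR: 0 of 13152 in sorted cells (smallest adjusted p = 0.347, 806 at an unadjusted p under 0.05) and 0 of 15644 in input (smallest adjusted p = 0.112, 512 at an unadjusted p under 0.05). DESeq2 called 19 and 8 genes and limma voom 0 and 0. Within sorted cells 4094 genes changed with genotype in F and 3822 in M, of which 2722 were shared and 2719 of these changed in the same direction. In input the counts were 3379 and 2527, with 1966 shared and 1965 in the same direction. These counts come from the interaction fit, which takes the spread from both letters, and differ from those of a letter fitted alone.

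Lists of interferon-response (median 1.38), MHC-II (2.26), monocyte (2.58), neutrophil (2.28) and border-associated macrophage (1.12) genes had a more positive APP129/PSEN1 minus WT difference in M than in F sorted libraries by camera (adjusted p = 5.4e-09, 2.14e-08, 2.59e-07, 2.29e-06 and 6.05e-07). With an estimated correlation these gave adjusted p = 0.592, 0.244, 0.244, 0.334 and 0.297, and the smallest fry adjusted p over all lists was 0.212. No member passed over all genes; adjusted over the list alone, 5 MHC-II and 8 monocyte genes passed and no interferon-response, neutrophil or border-associated macrophage gene. The disease-associated (median 0.14), senescence, NK cell (3.66) and erythroid (2.39) lists were more positive in M as well (adjusted p = 0.00102, 7.53e-05, 0.0138 and 0.00274; adjusted p = 0.623, 0.239, 0.239 and 0.297 with an estimated correlation), with 1, 1, 1 and 0 members adjusted over the list alone. The erythroid list did not pass without WT_positive replicate F2 (adjusted p = 0.0508) or M4 (0.0511). The MHC-I loading list had camera adjusted p = 0.044 (adjusted p = 0.833 with an estimated correlation), and without WT_positive replicate F2 its direction turned (adjusted p = 0.726). It also did not pass without APP_PSEN1_positive replicates F1, F2, M3 or M4 (adjusted p = 0.117, 0.141, 0.176 and 0.119) or WT_positive replicates M2 or M3 (0.26 and 0.136), each left out singly.

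In input the lists of MHC-II (median 2.02), interferon-response (0.97), border-associated macrophage (0.99), monocyte (0.94), neutrophil (2.19), T cell (1.34), NK cell (1.33) and erythroid genes were more positive in M than in F by camera (adjusted p = 7.92e-08, 1.35e-12, 7.73e-10, 4.08e-06, 2.93e-05, 0.000315, 0.0319 and 0.000315). The dissociation list was more negative in M (median -0.32, adjusted p = 0.000315). With an estimated correlation the monocyte and neutrophil lists gave adjusted p = 0.177 and 0.367 and the other 7 lists adjusted p = 0.335, and the smallest fry adjusted p over all lists was 0.538. No member passed over all genes; adjusted over the list alone, 4 MHC-II and 2 monocyte genes passed and none of the other 7 lists. The neutrophil list did not pass without WT_input replicate F4 (adjusted p = 0.103). The NK cell list did not pass without APP_PSEN1_input replicates F2, F4, M3 or M4 (0.052, 0.066, 0.0597 and 0.199) or WT_input replicates F4, M2 or M3 (0.103, 0.135 and 0.135), each left out singly.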

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

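The tests of other cell types carried into the sort, of the microglial share, of the WT input level of U05342 and of counts traded with Zfp91 were chosen after the results were seen.

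A gap rule was run on 72 sets of values, each a gene, list mean or total count within a group of libraries. In 4 of them a single value stood apart. The rule is set to flag about 1 in 20 sets by chance, so this many is near that rate. The sets overlap, and the rate was not measured here. All 4 belonged to WT replicate F2. Psmb8 was at 236 CPM in WT_positive replicate F2, with 134 to 158 CPM in the other libraries of that group, and the mean log2 CPM of the MHC-I peptide loading list was 7.81 there against 6.82 to 7.17. In WT_input replicate F2, H2-T22 was at 24.6 CPM against 14.7 to 16.9 CPM, and the same list at 6.45 against 5.46 to 5.75. Without WT_positive replicate F2, 24 MHC-I genes were called in place of 14.

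The genotype difference itself differed between sorted cells and input for 4749 genes. The differences, sorted cells minus input on the log2 scale, were -1 for H2-T24, -0.94 for B2m, -0.37 for Pdia3, -0.96 for Lilrb3, -0.58 for Tapbp and -1.11 for Pilra. They were -0.59 for App, -0.55 for Psen1 and 3.43 for Prnp.

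Gfap, Cspg4 and Flt1 were far higher in APP129/PSEN1 than in WT sorted cells, and cells carried through the sort would bring their other abundant transcripts too. Gfap gained 16.3% of its input level, while 12 other astrocyte genes gained a median of 0.136% (highest 1.02%, Aldh1l1), and Slc1a2, the most abundant, stood at 15.3 CPM in APP129/PSEN1 and 17.9 CPM in WT sorted cells. Cspg4 gained 60.4% against a median of -0.00512% over 10 other precursor genes (highest 0.446%, C1ql1), with Olig1 at 0.605 and 0.942 CPM. Flt1 gained 67.3% against a median of -0.797% over 8 other endothelial genes, with Slc2a1, which is also a glycolysis gene, highest at 12%. These values argue against carried cells of all 3 kinds, and expression of these genes in the Cd11b-positive cells themselves may be an explanation that stays open and untested.

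Of 43 measured MHC-I genes 21 were called higher in the APP129/PSEN1 input, where microglia may also have made up more of the RNA. The receptor list did not pass camera there, nor did the chain and loading lists with an estimated correlation. With the share set by homeostatic genes and no change per cell, the 21 MHC-I genes called higher lay 0.34 above the prediction on the log2 scale in the median (95% bootstrap interval over animals 0.01 to 0.68). Choosing them by that call raises this value. Over all 43 measured members the median was 0.07 (-0.2 to 0.5), so share alone stays open for the members as a set. In sorted cells Lilrb4 and H2-T22 were called higher and H2-T24 lower, so not every gene was unchanged per cell. Adding the levels measured in sorted cells left 0.01 (-0.04 to 0.06) over the 21 and 0 (-0.09 to 0.05) over the 43. This prediction uses the share and sorted levels of the same animals. For a gene read mostly from the sorted cells, a value near 0 is therefore largely built in. Single genes differed: Lilrb4, H2-D1 and H2-M3 lay 3.77, 1.08 and 0.92 above share alone, and Calr and Pdia3 at 0.05 and -0.04 from it. The share takes the homeostatic genes as microglial and unaltered by the sort, which was not tested, so share together with the sorted-cell levels stays open too.

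U05342, a transcript of unknown function, stood at 30.5 ± 4.53 CPM in WT sorted cells and 0.0692 ± 0.0618 CPM in APP129/PSEN1 sorted cells, but at 0.47 CPM in WT input, where the median animal held 8.67% (4.84 to 14.6%) of the level needed if the sorted cells already carried it. It was the single gene of 8043 at 10 CPM or more in WT sorted cells with under 25% of the needed input, against 0 of 8254 in APP129/PSEN1, which argues against transcripts present before the sort. Zfp91, which overlaps it on the same strand, was 19.8 CPM higher in APP129/PSEN1 (95% bootstrap interval 8.35 to 32.4), and the sum of both differed by -10.6 CPM (-25.2 to 4.93), so estimated counts traded between the overlapping genes may account for it. A test set earlier looked for a neighbour that fell as well and found none (lowest log2 fold change 0.26), but its bound was wrong, since counts traded between overlapping genes move them apart. A response to the sort in WT cells stays open and untested.

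For each comparison 100 splits were fitted, the real one included, with genotype shuffled among animals of a letter. With 100 splits the bound is 1 in 100 at best. Shuffled groups mix the genotypes, which raises their spread and lowers their calls, and the splits do not address the difference in depth. In sorted cells 1 of 100 splits, the real one, called as many as 5834 genes (highest other 1323). In input 1 of 100 called as many as 5310 (highest other 1), so no other drawn split reached the real count in either fraction. The same held for fraction, where splits swapped the fractions within animals and so parted as many pairs as the real one (1 of 100; 12985 genes, highest other 11494), and for genotype by fraction (1 of 100; 4749 genes, highest other 620). For the letter interaction edgeR called 0 genes in the real split, which 100 of 100 splits reach by construction (highest other 24 in sorted cells and 2 in input), so the splits decide nothing there.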

How the results depend on the processing

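Thinning to the smallest library, the member counts of MHC-I genes outside the planned settings, the lists under the covariate or thinned, and the fits of fraction without the letter were chosen after seeing the data. Where a value below changed, the cause was not tested, except where fewer samples, a stricter threshold or the covariate itself explains it by construction.

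In sorted cells 14 MHC-I genes were called, and 8 at an adjusted p of 0.01, 6 with F libraries alone, 8 with M libraries alone and 9 with the cell-mixture covariate. Leaving out a replicate gave 11 to 24, the highest without WT_positive replicate F2. In input 21 were called, and 10 with F libraries alone and 12 with the covariate (18 to 23 with a replicate left out). With genotype, 5834 genes were called in sorted cells and 3248 with M libraries alone (5278 to 5828 with a replicate left out), and in input 5310, against 2510 with F alone, 2259 with M alone and 1094 with the covariate (4614 to 5552). Thinned to the smallest library, sorted cells gave 5209 genes and input 5069.

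The MHC-I chain and loading lists in input (camera adjusted p = 0.000117 and 0.000132) gave adjusted p = 0.469 and 0.461 with an estimated correlation, and 4.68e-06 to 0.00141 and 4.1e-07 to 0.000439 with a replicate left out. In sorted cells the chain, loading and receptor lists stayed above the threshold, at 0.0707 to 0.55, 0.127 to 0.853 and 0.358 to 0.597, and the receptor list in input at 0.0789 to 0.281. The homeostatic list in input turned downward with the covariate (adjusted p = 0.879), which is that list's own level, and ran from 0.000463 to 0.00657 with a replicate left out.

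For the letter interaction DESeq2 called 19 genes in sorted cells and 8 in input, where edgeR called 0. Leaving out a replicate gave 0 to 1 (1 without APP_PSEN1_positive replicate M1) and 0 to 2 (2 without APP_PSEN1_input replicate M1). The MHC-I loading list of this interaction in sorted cells (adjusted p = 0.044) ran from adjusted p = 0.000854 without WT_positive replicate F3 to 0.726 without WT_positive replicate F2, the last with the direction turned. The MHC-I chain and receptor lists of the interaction did not pass in sorted cells (adjusted p = 0.199 and 0.176) or input (0.331 and 0.0778), and the loading list did not pass in input (0.798). The chain list passed without WT_positive replicates F3 or M4 (0.0162 and 0.000538), APP_PSEN1_positive replicates F3 or M2 (0.0344 and 0.0354), APP_PSEN1_input replicates F3 or M2 (0.00167 and 0.0232) or WT_input replicate M4 (0.00359). The receptor list passed without APP_PSEN1_positive replicate F4 (0.0406), APP_PSEN1_input replicates F3, M1 or M2 (0.0136, 0.0406 and 0.00617) or WT_input replicates F3 or M4 (0.0154 and 0.00506). Over all lists of the interaction, leaving out a library gained a call in 16 cases in sorted cells and 33 in input. Genotype by fraction called 4749 genes and 2997 at an adjusted p of 0.01 (4227 to 4812 with an animal left out), and fraction 12985 (12735 to 13015). Myzap ran from -5.33 to 0.46, the last without WT replicate M2, and Dusp14 from -5.56 to 1.46, the last without WT replicate M3. In the fraction comparison the median of all genes moved from -0.13 to -0.24 with DESeq2 size factors and to -0.31 with library size alone.

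Libraries with the same letter and number in both genotypes were compared by their residuals from the genotype and letter fit. These correlated at -0.327 to 0.0584 in input and -0.198 to -0.051 in sorted cells. In each fraction 0 of 12 libraries correlated best with its own number. By construction such residuals lean negative between opposite genotypes of the same letter, and positive between opposite genotypes of different letters. Both checks therefore cannot decide whether a shared number pairs libraries. With letter and number as a replicate block 5093 genes were called in sorted cells and 4223 in input, and 12 and 17 MHC-I genes. The letter interaction stayed at 0 genes by edgeR. With the animal as a replicate block, where the samples are paired, fraction called 12865 genes and genotype by fraction 4792, and the block changed no call of an MHC-I list. With an animal left out, single named genes kept their direction and side of the threshold in 1712 cases in sorted cells, with 68 lost and 22 gained, and in input in 1786 cases, with 57 lost and 17 gained. Pseudocount and filter alternatives planned for normalized values were not run, since the tables hold counts. Depth limits genes of low level most in WT sorted libraries, the shallowest group (13100296 counts on average).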

Other observations

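The test of the microglial share was chosen after the results were seen.

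Some genes of the T cell and border-associated macrophage lists fell in APP129/PSEN1 sorted cells, though the lists did not pass. Il7r, the interleukin-7 receptor chain, fell from 187 ± 14.2 CPM (SD, n = 6) in WT to 44 ± 21.1 CPM (SD, n = 8), and Cd4 fell by 1.77 ± 0.394 on the log2 scale. Between the fractions Il7r was higher in sorted cells (2.19 ± 0.236), while Cd3e and Cd3g were lower (-4.99 ± 0.635 and -4.73 ± 0.611). The fall of Il7r is therefore not read as a loss of T cells. The T cell list had 0 higher and 3 lower of 4 (camera adjusted p = 0.146, but 0.0367 without WT_positive replicate M4). Stab1, a scavenger receptor of border-associated macrophages, fell from 513.7 ± 121 to 263.6 ± 120.2 CPM. That list had 0 higher and 3 lower of 11 (adjusted p = 0.218), and none adjusted over the list alone. Among interferon-response genes Lgals3bp rose 3.65-fold and Bst2 2.33-fold and Gbp3 fell by 2.06 ± 0.375. The list had 10 higher and 1 lower of 32 (adjusted p = 0.288, but 0.0134 without WT_positive replicate F2), and 5 higher and 1 lower adjusted over the list alone. The stress-response transcription factors Atf3 and Egr2 rose 5.43-fold and 7.39-fold, in a dissociation list with 8 higher and 3 lower of 22 (adjusted p = 0.26, but 0.0215 without WT_positive replicate M2).

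The other lists of the sorted genotype comparison did not pass camera. MHC-II had 1 higher of 9 (adjusted p = 0.923), complement 2 higher and 4 lower of 12 (0.923), cell cycle 2 higher of 20 (0.923; 1 adjusted over the list alone), transgene-related genes 1 higher of 4 (0.0975), X-inactivation and Y-linked genes 1 lower of 5 (0.77) and reactive astrocytes 4 higher and 1 lower of 12 (0.229). Oligodendrocyte precursors had 1 higher of 5 (0.409), ependymal and choroid plexus cells 1 higher of 3 (0.953), monocytes 1 higher and 3 lower of 10 (0.397; 3 lower adjusted over the list alone), neutrophils 1 higher and 1 lower of 10 (0.457; 1 higher adjusted over the list alone), NK cells 1 higher of 3 (0.972) and erythroid cells 2 lower of 3 (0.409). Fewer than 3 B cell genes were measured in sorted cells. The other lists of this paragraph had the same counts adjusted over the list alone.

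In input, lipid droplet genes were higher in 9 of 16 (camera adjusted p = 7.01e-06; adjusted p = 0.202 with an estimated correlation), among them Plin2, a lipid droplet coat gene, 2.22-fold, and 9 were higher and 1 lower adjusted over the list alone. Glycolysis genes were higher in 6 of 16 (adjusted p = 0.00951; adjusted p = 0.609 with an estimated correlation), with the lactate transporter Slc16a3 6.28-fold. The senescence list was higher in 13 and lower in 5 of 33 (adjusted p = 0.00109; adjusted p = 0.398 with an estimated correlation). Lists that did not pass were dissociation (6 higher, 2 lower of 22; adjusted p = 0.146, but 0.0454 without WT_input replicate M3), transgene-related (2 higher, 1 lower of 4; 0.21), X-inactivation and Y-linked (0 of 5; 0.969), oligodendrocytes (1 lower of 14; 0.312), precursors (1 higher, 3 lower of 12; 0.264, but 0.0427 without APP_PSEN1_input replicate F2) and endothelial cells (2 lower of 14; 0.0507). The endothelial list passed without APP_PSEN1_input replicates F1, F2 or M1 (adjusted p = 0.0185, 0.0427 and 0.0171) or WT_input replicates F2, M3 or M4 (0.00239, 0.0454 and 0.0198), each left out singly. No call was made either for mural (0 of 10; 0.641), ependymal (0 of 10; 0.969), border-associated macrophages (2 higher of 11; 0.612), monocytes (0 of 10; 0.685), neutrophils (1 higher of 10; 0.685), T cells (1 lower of 8; 0.411), NK cells (1 higher of 5; 0.641), B cells (1 higher, 1 lower of 3; 0.871) and erythroid cells (0 of 4; 0.685). Counts adjusted over the list alone differed for dissociation (6 higher, 3 lower), oligodendrocytes (0) and border-associated macrophages (1 higher). No mitochondrially encoded gene was in the tables.

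The share of input RNA from microglia was estimated for each animal as the median, over 17 homeostatic genes, of the input level over the sorted level. It was 38.6 ± 6.55% (SD, n = 8, range 30.2 to 50.2) in APP129/PSEN1 and 17.7 ± 1.02% (SD, n = 6, range 15.8 to 18.7) in WT, a ratio of 2.18 (exact two-sided permutation test, p = 0.000333). Share alone was not excluded as the source of the higher MHC-I levels for the members as a set, with the called MHC-I genes 0.34 and all measured ones 0.07 above its prediction. Lists of other cells did not fall alike in input, with median log2 fold changes of -1.20 for astrocytes, -0.73 for neurons, -0.16 for oligodendrocytes, -0.08 for mural cells and 0.16 for ependymal and choroid plexus cells.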
